A study of Homo sapiens with 2 samples.

How the data were processed

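Total RNA of parental U87MG cells and of a TMZ-resistant clone was labelled with biotin and hybridised to Illumina expression beadchips, 1 array each, per the labels. The deposited signals are mean bead intensities per probe on a linear scale, which the authors' file names as not normalized; no signal is negative, with minima of 90.3 and 65.8. Per the file headers, each probe also has the standard error over its beads, its number of beads and a detection p-value on each array. The detection p-values move in steps of 1 in 770, as a rank among that many negative controls gives. The scanner software is not given in the sources used here. The authors also deposited a table of processed intensities of the same 47321 probes. Its values have the same rank order as the signals of each array (Spearman correlation 1), are on a linear scale and are brighter where the signal is brighter. Its sorted columns differ by at most 0.0186 on the log2 scale, as after quantile normalization, and the column medians are 98.8 and 98.7. What target the authors scaled to stays unknown, since the mean of the medians of the signals is 105. Columns were matched to samples by the titles in the header; 2 lines that hold no probe were left out.

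Signals were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the negative control mean and variance inferred from the detection p-values and an offset of 16, then quantile normalized between the 2 arrays and taken to log2. A probe was called detected at a detection p under 0.01. A gene entered where a probe was detected on at least 1 array, and its brightest detected probe by mean log2 value stood for it. Quantile normalization gives both arrays the same distribution of values. Where 1 array has far fewer probes above background, the faint detected probes of that array are thereby raised, and a probe can be called higher although its signal is lower. Signals on the parental and then the resistant array are therefore printed for the genes named as higher.

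Probes were named through the platform annotation, updated by gene identifier to the symbols of a GRCh38.p14 gene table, which was used for names only. Of all probes, 30113 had 1 symbol, 8 had several and 17200 had none here; 30070 symbols were found by gene identifier, and the named probes covered 20046 genes. Probes with several symbols or none were not named. Probe positions and sequences were not used here, so probes that read near-identical transcripts could not be separated.

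With 1 array per group, no test between groups can be made, and genes were counted by a fixed size, a log2 difference of at least 1. A probe detected on 1 array only gives a bound, the bright value against the higher of the dim probe's own value and the lowest value among detected probes of the dim array, and is written as at least N-fold. Such a bound holds on the scale of the normalization; where the signal is not clearly higher on the resistant array, it is given as a normalized value or left out. No fold is given where that bound is under 1, and such genes are counted in neither direction. The precision of a difference was described by the robust SD of the disagreement between 2 probes of the same gene, divided by the square root of 2. Only pairs with both probes detected on both arrays entered. Shares of probes carry 95% Wilson intervals, which cover counting error only.

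Before the data were examined, 42 gene lists were fixed for pathways, repair, stress, cell types and controls, with 1231 entries, of which 1147 matched a named probe. List members were counted as higher or lower at 1.5-fold, and lists with at least 5 detected members were set against 10000 random lists drawn from 10 bins of mean expression. Lists were said to stand apart under percentile 2.5 or above 97.5. The genes to be named were fixed by rule at the same time. They are the 12 highest and 12 lowest among genes detected on both arrays, the 6 highest and 6 lowest bounds, the up to 3 members of each list with the largest absolute difference, and 5 genes of TMZ damage repair, of which 2 were not analysed here. Clone-type and blank names were skipped.

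The alternatives fixed beforehand were no background correction, an offset of 50, median centring, cyclic loess, a detection p under 0.05, detection on both arrays, no filter, the mean over a gene's detected probes, the probe with the smallest difference, and the authors' table. Leaving out the between-array step and the share of parental-detected probes detected on both arrays were added after the data were seen. So were the value of a gene's main probe under each scaling and the count of other probes of the named higher genes.

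The steps were also tested on simulated data. In an array simulated from the parental one with known changes, the calls were right for 62 of 62 genes lowered to 0.25, 68 of 68 lowered to 0.4, 76 of 76 raised 2.5-fold, 79 of 79 raised 4-fold and 13120 of 13120 unchanged genes. That simulated array kept the background and brightness of the parental one, and only probes of middle signal were changed. It therefore tests the steps between 2 similar arrays, not the calls on the far dimmer resistant array. In a further simulation the unchanged parental array was dimmed until 2898 probes were detected. Of 10033 genes, 311 were then called higher and 4 lower with quantile normalization, and 0 higher and 9309 lower without a between-array step. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.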

Results

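Gene expression was measured in parental U87MG cells, a human glioblastoma line, and in a temozolomide-resistant clone selected from it (clone 10). Temozolomide (TMZ) is an alkylating drug used against glioblastoma; it methylates DNA, and its most toxic lesion is repaired by MGMT or recognised by mismatch repair. The comparison asks which transcripts differ between the resistant clone and its parental line. Each group was 1 Illumina expression beadchip with 47321 probes, hybridised with biotin-labelled cRNA from total RNA. With 1 array per group, no difference below has a replicate check or a p-value, and the number of arrays limits the precision.

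On the parental array 16109 probes were detected (34.0%, 95% Wilson interval 33.6 to 34.5%), and on the resistant array 2898 (6.12%, 5.91 to 6.34%). The median signal was 125 on the parental and 85.0 on the resistant array, and 3295 against 301 probes had a signal above 1000. The brightest probe of each array had a similar signal, 21860 and 20611. The median probe rested on 22 beads on both arrays. Among the probes detected on each array, the median bead standard error was 4.37% of the signal on the parental and 4.404% on the resistant array. Of all probes, 2185 were detected on both arrays, 13924 on the parental array only and 713 on the resistant array only. A false detection rate of 0.01 alone gives 312 of the last kind. Across the probes detected on both arrays, which are not independent replicates, log2 signals correlated at Pearson's r = 0.59.

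Many transcripts that are abundant in most cell types gave background signal on the resistant array. Metallothionein MT2A had a signal of 19502 on the parental array and 88.4, undetected, on the resistant array. The ornithine decarboxylase antizyme OAZ1 went from 19431 to 73.2, the ribosomal protein gene RPL41 from 17898 to 84.9 and the glycolytic enzyme ENO1 from 17481 to 95.5. Of the 401 probes above 8000 on the parental array, 228 (56.9%) were undetected on the resistant array and 173 (43.1%, 38.4 to 48.0%) were detected. Meanwhile 1480 probes at or below 1000 on the parental array were detected on both. The probes above 1000 on the parental array had a median of 22 beads on the resistant array, whether detected there (705 probes) or undetected (2590 probes).

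Probes of the same gene often disagreed on the resistant array. The genes in this paragraph were chosen after their values were seen. For ACTB, cytoplasmic beta-actin, 3 probes had parental signals of 15130, 16368 and 16179. On the resistant array they had 941, 85.0 and 92.3, and only the probe at 941 was detected. For GAPDH the parental signals of 13283, 7665 and 17205 stood against 318, 89.2 and 94.0, with the probe at 318 alone detected. Both probes of beta-2-microglobulin, B2M, were undetected, at 91.1 and 84.8 against 11780 and 6417 on the parental array. Of the 28 probes of the housekeeping list, all 28 were detected on the parental and 7 on the resistant array.

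**Figure D1:**
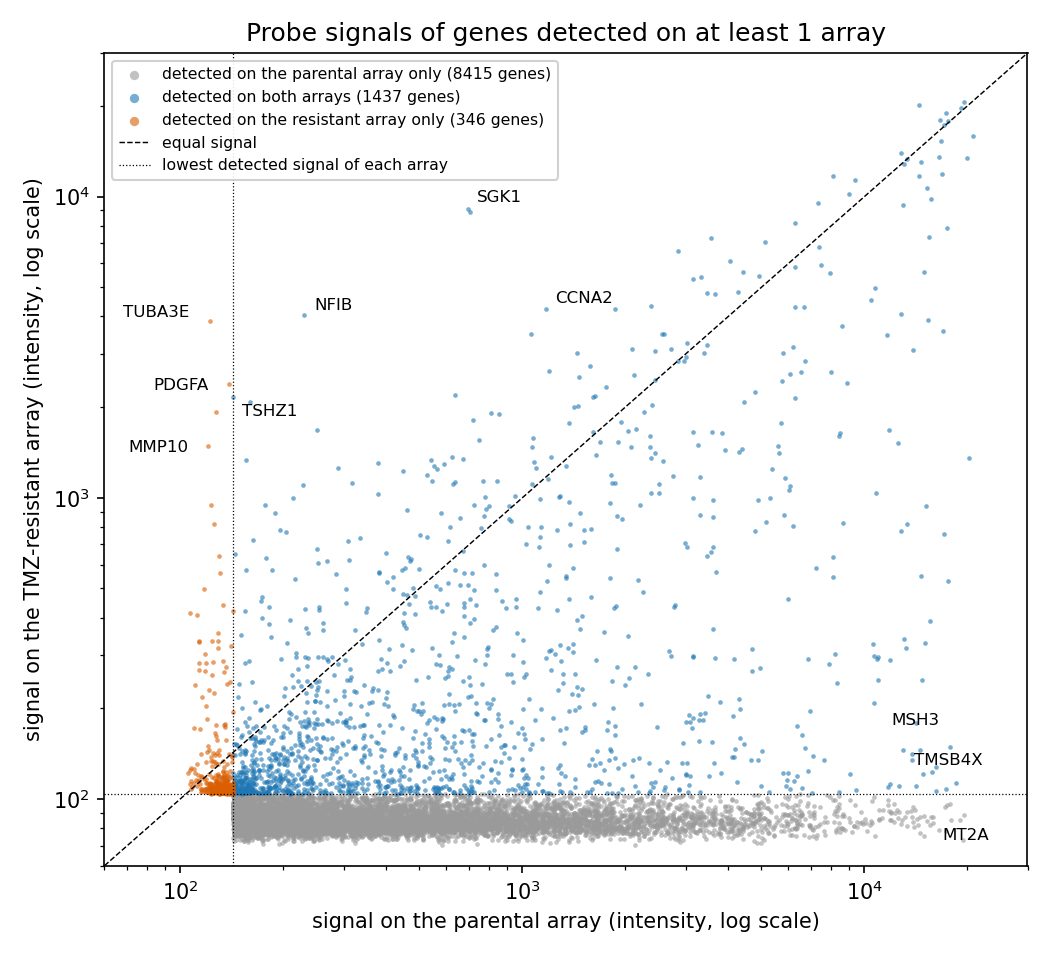
Signal of each gene's chosen probe on the parental (horizontal) and resistant array (vertical), both as linear intensity on log axes, for the 10198 genes detected on at least 1 array. Points are coloured by the arrays that detected them, 8415 on the parental array only, 1437 on both and 346 on the resistant array only; dotted lines are the lowest detected signals, 143 and 104, and the dashed line marks equal signal.

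**Figure D2:**
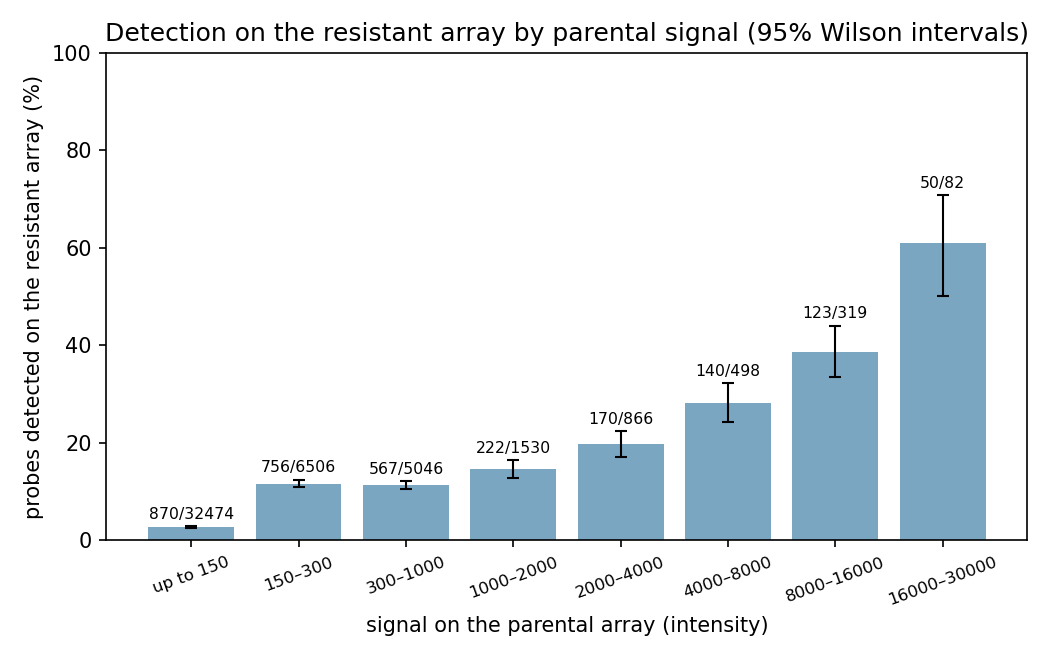
Share of probes detected on the resistant array (vertical, percent) by their signal on the parental array (horizontal, linear intensity), with 95% Wilson intervals as error bars and the numbers of probes above the bars. The share reached 61.0% (50.2 to 70.8%) for the 82 probes above 16000 and was 11.2% (10.4 to 12.1%) for those from 300 to 1000.

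After background correction and quantile normalization, 1548 of 10198 genes were at least 2-fold higher in the resistant clone and 667 at least 2-fold lower, so that 69.9% of the calls were higher. TSHZ1, SGK1, NFIB, TIMP2 and PDGFA stood among the highest, and MT2A, OAZ1, ANXA2, TMSB4X and many ribosomal protein genes among the lowest. Among the 1437 genes detected on both arrays, 1202 were higher and 64 lower, around a median log2 difference of 2.62. This balance followed the scaling. With median centring 957 genes were higher and 4364 lower (18.0% higher; median 0.91 among genes on both arrays), with cyclic loess 1671 and 0 (100%; median 4.06). With no between-array step, an alternative added after the data were seen, the counts were 125 and 8056 (1.53% higher; median -1.19). The authors' own normalized values gave 1548 and 681. Many genes called higher had a lower signal on the resistant array, 1013 of the 1202 detected on both arrays (84.3%) and 261 of the 346 detected on the resistant array only (75.4%). All 346 were counted as higher by their normalized bound, and 603 of the 8415 detected on the parental array only were counted as lower by their bound. The lowest detected log2 level was 4.91 on the parental and 7.56 on the resistant array after normalization. Any gene detected on the resistant array only was therefore bound to be counted as higher. A gene detected on the parental array only could be counted as lower only where its parental level lay at least 1 above 7.56. The others were counted in neither direction, which does not show that they were unchanged.

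Under 6 scalings (the main one, no background correction, an offset of 50, median centring, no between-array step and the authors' values), 125 genes were at least 2-fold higher and 476 at least 2-fold lower throughout. The 125 are all the genes called higher without a between-array step. The main setting, no background correction, an offset of 50 and the authors' values share most higher calls, so these are not 6 separate checks. Cyclic loess is not among the 6 scalings and called 0 genes at least 2-fold lower, so that no lower call given below held at 2-fold under it. The spread between 2 probes of the same gene, as the robust SD of a log2 difference, was 1.004 (103 probe pairs). This SD covers only pairs with both probes detected on both arrays. It leaves out genes with a probe lost on the resistant array, and the spread between cultures or clones. By a count added after the data were seen, 81 genes named by the fixed rule were at least 1.5-fold higher, and 30 of them had another probe detected on the parental array. In 25 of the 30, every such probe was undetected on the resistant array. Besides the genes whose other probes are given below, these were KMT2E, RFC4, LIG3, RAD51C, BAX, SOD2, CPT1A, KLF4, ID2, MYC, COL6A2, COL12A1, BCL2, BCL2L1 and TUBB, and their higher calls rest on 1 probe each.

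The largest positive differences among genes detected on both arrays were those of TSHZ1, RNU11, NFIB, TIMP2, SGK1, TUBA3D, PABPC3, KMT2E, LMNB1, H3C14, FOSB and HYLS1, and all 12 were at least 2-fold higher under the 6 scalings. TSHZ1, a zinc-finger homeobox transcription factor, had a signal of 143 on the parental and 2161 on the resistant array, a normalized difference of 7.45 (175-fold). That parental signal lay at the lowest detected one of the array, 143, so the fold rests on a value at the floor. The parental signals of KMT2E, TIMP2, RNU11 and H3C14 lay near it too. NFIB, a nuclear factor I transcription factor of glial development, went from 229 to 4057 (143-fold), and its other probe from 290 to 1144. SGK1, a serum- and glucocorticoid-induced kinase, went from 695 to 9132 (94.4-fold), but its other 3 probes were undetected on the resistant array. TIMP2, an inhibitor of metalloproteases, went from 156 to 1334 (109.8-fold), while its other probe went from 917 to 87.3, undetected. The small nuclear RNA of the minor spliceosome, RNU11, went from 159 to 2079 (143-fold), with its other probe at 146 and 1772.

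TUBA3D, an alpha-tubulin gene, went from 704 to 8904 (92.4-fold), and PABPC3, a poly(A)-binding protein gene, from 251 to 1679 (74.99-fold). Both have near-identical family members, so their probes may read other transcripts. KMT2E was 69.3-fold (145 and 649), LMNB1, nuclear lamin B1, 68.9-fold (177 and 944) and H3C14, a histone H3 gene, 62.5-fold higher (163 and 727). The immediate early transcription factor FOSB was 60.8-fold (189 and 892) and HYLS1 59.9-fold higher (228 and 1105). Of the 11 other probes of the 12 genes, 2 were detected on the resistant array, those of NFIB and RNU11. Without a between-array step the differences were smaller, such as 5.64 for TSHZ1, 4.95 for NFIB and 3.93 for SGK1.

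Genes detected on the resistant array only were given as bounds, which hold on the quantile-normalized scale. PDGFA, a platelet-derived growth factor subunit, had a signal of 139 on the parental array, under its lowest detected signal of 143, and 2394 on the resistant array, at least 187-fold higher. Of its other 2 probes, 1 was detected on the resistant array, at 166. CRYAB, the small heat shock protein alpha-B crystallin, was at least 163-fold higher (127 and 1923) and MMP10, the metalloprotease stromelysin-2, at least 136-fold higher (120 and 1491). ISL1, a LIM homeobox transcription factor, was at least 83.9-fold higher (125 and 816). TUBA3E (at least 252-fold; 122 and 3867) and CYCSP52 (at least 94.9-fold; 123 and 947) belong to a tubulin family and to cytochrome c pseudogenes, and their probes may read near-identical transcripts. The bounds moved with the scaling. Without a between-array step the log2 bound was 5.80 for PDGFA, 5.47 for CRYAB, 5.09 for MMP10, 4.16 for ISL1, 6.50 for TUBA3E and 4.39 for CYCSP52, against 7.55, 7.35, 7.09, 6.39, 7.98 and 6.57 under the main setting. With the authors' values it was 5.84 for PDGFA and 5.72 for CRYAB, and with median centring 7.90 and 7.57.

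The lowest genes among those detected on both arrays included ribosomal protein genes and other transcripts bright on the parental array. TMSB4X, the actin-binding thymosin beta-4, had a signal of 18534 on the parental and 113 on the resistant array (61.8-fold lower). RPL38 was 60.01-fold lower (17362 and 108), RPL9 31.2-fold, RPL37A 20.4-fold, RPL35A 18.0-fold, FAU 15.99-fold and RPS6 15.4-fold. ATP5F1B, the catalytic beta subunit of mitochondrial ATP synthase, was 25.1-fold lower (15721 and 123), and the annexin pseudogene ANXA2P2 45.4-fold. The resistant signals of all 12 lay close to its lowest detected signal of 104, from 106 for ANXA2P2 to 148 for RPL9. All 12 were lower under the 6 scalings and higher under cyclic loess, by 0.90 for ANXA2P2 to 2.94 for RPL9.

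Probes named LAIR1 (25.6-fold lower), CLUAP1 (23.7-fold) and MSH3 (13.5-fold) were also in this group. LAIR1 had a parental signal of 16222 and CLUAP1 of 14184 on this probe, and the genes' other probes had far less. For MSH3, a mismatch repair gene, the signals were 14552 and 145, and its other probe had 309 and 90.4. For CLUAP1 the other 4 probes had parental signals of 144, 187, 214 and 268, and for LAIR1 the other probe had 144. Of the 12 other probes of the lowest 12 genes, 11 were detected on the parental array and 0 on the resistant array. Among genes detected on the parental array only, MT2A was at least 97.7-fold lower, OAZ1 at least 96.6-fold, ANXA2 at least 95.04-fold, RPL41 at least 81.9-fold, the alpha-tubulin gene TUBA1B at least 81.5-fold and ENO1 at least 75.3-fold.

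The genes of TMZ damage repair fixed in advance gave few usable levels. MGMT, which removes the methyl group from the O6 position of guanine, was undetected on both arrays, with signals of 124 and 80.1. MSH6 had 1524 on the parental array and 75.7, undetected, on the resistant array, a bound of at least 1.23-fold lower in the main setting. Its log2 bound was -3.29 with median centring and -5.39 without a between-array step. PMS2 was detected on the parental array only, at 299 against 85.3, and the main setting allowed no fold; its bound was -0.45 with median centring and -2.55 without a between-array step. Of the mismatch repair list, 18 members were detected on the parental and 3 on the resistant array, with 2 members higher and 3 lower by at least 1.5-fold. RFC4 was 5.01-fold higher by normalized value although its signal was 1213 and 268, and its sign turned under median centring (-0.39) and without a between-array step (-2.49). RPA3 was at least 4.65-fold lower (4669 and 88.4).

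In direct reversal and base excision repair, 5 of 20 detected members were detected on the resistant array; 5 were higher and 2 lower. TDG, a thymine DNA glycosylase, was 23.9-fold higher (766 and 1137) on the chosen probe, with 0.68 without a between-array step, while its other probe went from 367 to 83.3, undetected. By normalized value LIG3 was 5.88-fold (171 and 108) and ALKBH2 4.38-fold higher (389 and 129), but both turned negative without a between-array step. In homologous recombination and the Fanconi anemia pathway, 3 of 21 were detected on the resistant array, and 1 other member was lower. By normalized value BARD1 (7.17-fold; 345 and 163), XRCC2 (2.57-fold; 868 and 132) and RAD51C (1.84-fold; 686 and 109) were higher. All 3 turned negative without a between-array step (-1.40, -3.63 and -3.92), and XRCC2 and RAD51C also under median centring (-1.53 and -1.82). Of 7 detected drug efflux transporters, 0 were detected on the resistant array, and ABCA1 was at least 7.004-fold lower. ABCC4 and ABCC2 had no fold in the main setting, bounds of -2.22 and -0.70 with median centring, and -4.32 and -2.80 without a between-array step.

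Among p53 target genes, 4 of 24 were detected on the resistant array. These 4 were higher, as most genes detected there were, and 3 others were lower. MDM2, the ubiquitin ligase that restrains p53, was detected there only (131 and 562), at least 62.6-fold higher (log2 bound 3.56 without a between-array step and 5.97 under the main setting). BAX (14.5-fold) and BBC3 (14.1-fold), pro-apoptotic members of the BCL2 family, had nearly equal signals on the arrays, 538 and 452 for BAX and 208 and 194 for BBC3. Without a between-array step their differences were -0.19 and 0.21. Both also made up the higher members of the pro-apoptotic list (2 higher and 1 lower of 14), where DIABLO was at least 1.96-fold lower (-6.14 without a between-array step). In the anti-apoptotic list 2 of 10 were higher, BCL2 (13.2-fold by its normalized bound, 119 and 133) and BCL2L1 (12.6-fold, 2359 and 1603). Without a between-array step they had 0.58 and -0.56. BAG3 was at least 1.16-fold lower in the main setting (-5.27 without a between-array step).

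In the cell cycle and mitosis list, 5 of 36 members were detected on the resistant array, 3 were higher and 4 lower. CCNA2, cyclin A2, was 41.9-fold higher (1176 and 4223) and the mitotic kinesin KIF23 31.7-fold higher (591 and 1296), both also without a between-array step (1.95 and 1.32). PTTG1, securin, was at least 7.83-fold lower (6378 and 95.4). In DNA replication 2 of 28 were detected on the resistant array, with 1 higher and 7 lower. ORC6 was at least 21.8-fold and RRM1 at least 4.27-fold lower, and PRIM1 was 12.8-fold higher (581 and 421) on the chosen probe, with a turned sign (-0.45) without a between-array step. The other PRIM1 probe went from 624 to 87.6, undetected. Among histone genes 4 of 19 were higher and 2 lower, with H4C3 at least 18.5-fold lower, H2AC25 10.96-fold higher (237 and 176) and H2AC8 9.71-fold higher by its normalized bound (114 and 115). Without a between-array step H2AC25 had -0.37 and H2AC8 0.10.

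Oxidative phosphorylation had 31 detected members, 20 lower and 0 higher, with 5 detected on the resistant array. Besides ATP5F1B, COX4I1 was at least 14.7-fold and NDUFB3 at least 12.7-fold lower. Hypoxia and glycolysis genes went both ways, 6 higher and 9 lower of 32. ENO1 and LDHA (at least 22.3-fold lower) stood against PKM, pyruvate kinase, which was 35.3-fold higher (717 and 1807) on the chosen probe and lower (-0.46) on the probe with the smallest difference. The other 2 PKM probes went from 1750 to 78.9 and from 3644 to 81.4, both undetected on the resistant array. In fatty acid metabolism 4 of 21 were higher and 3 lower. SCD, stearoyl-CoA desaturase, was at least 16.1-fold lower (10023 and 86.0), SREBF1 15.1-fold higher (249 and 245) on the chosen probe and CPT1A 8.23-fold higher (162 and 117), with 0.23 and -0.40 without a between-array step. Another SREBF1 probe went from 611 to 80.3, undetected. In cholesterol biosynthesis 2 of 18 were higher, MSMO1 (11.1-fold; 231 and 175) and SREBF2 (7.15-fold; 146 and 107), and INSIG1 was at least 4.79-fold lower. SREBF2 turned sign without a between-array step. The chosen MSMO1 probe had 1.79 under median centring and -0.32 without a between-array step. Its other 2 detected probes went from 530 to 86.0 and from 1380 to 83.9, both undetected, and the last is the brightest under 3 scalings, with -3.14 under median centring.

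Stress and detoxification lists had more lower than higher members, except the aldehyde dehydrogenases. In the unfolded protein and integrated stress response, 15 of 33 were lower and 5 higher, with the transcription factor ATF4 at least 17.9-fold, the serine synthesis enzyme PHGDH at least 15.1-fold and MANF at least 11.9-fold lower. Among heat shock chaperones 5 of 16 were lower and 4 higher. HSP90AA1 was at least 22.2-fold lower, and DNAJA1 (14.5-fold; 4047 and 6097; 0.61 without a between-array step) joined CRYAB among the higher. NRF2 and glutathione genes had 12 of 32 lower and 3 higher. Thioredoxin, TXN, was at least 31.0-fold and SOD1 at least 15.6-fold lower, while SOD2 was 8.44-fold higher (2501 and 1041) and had -1.31 without a between-array step. For aldehyde dehydrogenases 2 of 9 were higher and 2 lower, with ALDH1A3 at least 12.6-fold and ALDH9A1 at least 4.31-fold lower. ALDH7A1 was 10.3-fold higher (873 and 454) on the chosen probe and -1.01 without a between-array step, while its other probe went from 894 to 84.8, undetected. In autophagy and lysosome 6 of 28 were lower and 3 higher, with SQSTM1 at least 30.5-fold and CTSL at least 21.6-fold lower and BECN1 22.2-fold higher (846 and 1133; 0.51 without a between-array step).

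Of the mesenchymal glioma and EMT list, 8 of 33 detected members were detected on the resistant array, 6 were higher and 11 lower. The calcium-dependent membrane binders ANXA2 and ANXA1 (at least 22.7-fold) and the metalloprotease inhibitor TIMP1 (at least 45.1-fold) were lower. Metalloproteases and inhibitors had 2 higher, MMP10 and TIMP2, and 4 lower of 23. Collagens and matrix proteins had 5 higher and 4 lower of 30. FBLN1, fibulin 1, was at least 41.3-fold higher (113 and 334) under the main setting. Its log2 bound was 2.66 without a between-array step and 4.37 with the authors' values, against 5.37. COL6A2 (8.35-fold; 405 and 204) and COL12A1 (6.71-fold; 157 and 109) were higher with turned signs (-1.19 and -0.55) without a between-array step. Among integrins 2 of 14 were higher and 2 lower. ITGB1, the common beta subunit, was at least 16.4-fold lower, and ITGA7 (7.29-fold; 146 and 108) and ITGA9 (6.05-fold; 155 and 106) were higher but -0.26 and -0.60 without a between-array step. YAP and SRF targets had 5 higher and 3 lower of 21, with SRF 17.8-fold higher (756 and 796; 0.15 without a between-array step), EGR1 6.70-fold higher (513 and 195; -1.72 without it) and FHL2 at least 5.65-fold lower.

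In signaling lists the genes detected on the resistant array were mostly counted as higher, as such genes were over the whole array. At 2-fold, 1202 of all 1437 genes detected on both arrays were called higher. So were all 346 genes detected on the resistant array only. In the receptor tyrosine kinase list 18 members were detected on the parental array only, and all 18 were counted in neither direction. Receptor tyrosine kinases and ligands had 4 higher and 0 lower of 22; after PDGFA these included DDR1 (5.56-fold; 183 and 109) and MET (3.67-fold; 811 and 159), which were -1.09 and -3.01 without a between-array step. MAPK feedback genes had 5 higher and 5 lower of 22, FOSB and FOS (13.4-fold by its normalized bound; 123 and 134; 0.60 without a between-array step) higher and cyclin D1, CCND1, at least 7.59-fold lower (6319 and 75.02). WNT signaling had 7 higher and 1 lower of 18. By normalized value FZD7 (12.2-fold; 205 and 172), CTNNB1 (11.7-fold; 477 and 313) and LRP6 (10.9-fold by its normalized bound; 129 and 121) were higher. Without a between-array step they had -0.037, -0.63 and 0.26. In TGF-beta and BMP signaling 2 were higher and 1 lower of 22, SKI 29.4-fold (159 and 287), ID2 7.22-fold (478 and 199; -1.55 without a between-array step) and FST at least 1.75-fold lower (-6.00 without it).

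Antigen presentation and cytokine probes were detected on the resistant array at shares inside the range of probes matched on parental signal (13.3%, percentile 43.8, and 3.85%, percentile 6.92), a measure added after the data were seen. CXCL8, interleukin 8, was at least 10.9-fold lower (7795 and 83.8). In the NF-kB and cytokine list 3 were higher and 3 lower of 23, and 2 of the higher were NFKB2 and CXCL10. NFKB2 had 129.7 and 140 (0.74 without a between-array step). CXCL10 had 135 on the parental and 110.2 on the resistant array, was counted as higher by its normalized value alone and allowed no fold without a between-array step. In the type I interferon list 3 of 27 were higher and 0 lower. The other 24 were detected on the parental array only and were counted in neither direction. IFIH1 was likewise counted by its normalized value alone, with signals of 138 and 111 and no fold without a between-array step. IFITM2 (2.12-fold; 1002 and 126) turned sign under median centring (-1.92) and without a between-array step (-4.02). IFI6 (5.60-fold; 345 and 139) had 0.28 and -1.82 on the same probe. Its other probe went from 1086 to 98.6, undetected, and is the brightest under both of these scalings, with -2.76 and -4.86. In antigen presentation 5 of 21 were lower and 2 higher. B2M was at least 20.8-fold and ERAP2 at least 8.26-fold lower. On the ERAP2 probe with the smallest difference the normalized value was 0.75 higher, although its signal went from 580 to 104.6. PSMB10 was 7.90-fold higher (1891 and 675) but -1.57 without a between-array step.

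Neural stem cell genes had 3 higher of 12, KLF4 (8.30-fold, 243 and 147), ID2 and MYC (3.75-fold, 1393 and 223). All 3 turned sign without a between-array step. The other 9 were detected on the parental array only and were counted in neither direction. In the astrocyte list 2 of 5 were counted as higher by normalized value, GLUL (139.7 and 111; no fold without a between-array step) and ALDOC (1.94-fold; 808 and 114). ALDOC had -1.91 under median centring and -4.01 without a between-array step, and GJA1, with no fold in the main setting, had -2.43 and -4.54. In the proneural and oligodendrocyte lineage list 2 of 5 were higher by normalized value, NCAN (13.2-fold; 172 and 156) and SOX4 (10.5-fold by its normalized bound; 134 and 119). Without a between-array step they had 0.28 and 0.21. BCAN had no fold in the main setting and -0.47 without that step. Neuronal genes had 4 lower of 13, among them UCHL1 (at least 6.31-fold) and VGF (at least 5.94-fold), and ELAVL3 was counted as higher by its normalized value alone (131 and 106; no fold without a between-array step). In blood and microglia markers 3 of 7 were counted as higher by normalized value alone, near the detection limit. CD79A had 133 and 123 (0.33 without a between-array step). SPI1 (115 and 108) and CD4 (118 and 106) allowed no fold without it, and the macrophage gene CD68, named after its value was seen, was lower (5268 and 106). HOX genes had 5 of 12 higher by normalized value, among them HOXB6 (10.2-fold; 152 and 123), HOXD3 (8.92-fold; 151 and 116) and HOXC6 (8.20-fold by its normalized bound; 125 and 109.9). HOXB6 had 0.03 and HOXD3 -0.14 without a between-array step, and the HOXC6 probe allowed no fold. Another HOXC6 probe went from 751 to 89.0, undetected, and is the brightest without that step (-4.27). Of 4 detected cancer-testis antigens SPANXB1 was counted as higher by its normalized value alone (134 and 105; no fold without a between-array step), and MAGEC1 and MAGEC2 had no fold in the main setting and -1.25 and -0.36 on the same probes without that step, which gave another MAGEC2 probe -1.73. The epithelial genes EPCAM and ELF3 and the endothelial genes ENG and TEK were detected on the parental array only, and none of the 4 allowed a fold in the main setting. Their bounds without a between-array step were -1.09, -0.45, -1.66 and -1.28.

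The 2 control lists also went both ways. Of 48 ribosomal protein genes, 22 were detected on the resistant array, 29 were lower and 7 higher. RPL8 (17281 and 78.0; at least 71.6-fold) and RPLP1 (at least 51.9-fold) were lower with RPL38. Of 16 housekeeping reference genes, 7 were lower and 3 higher, with TUBB (13.5-fold; 2073.5 and 1471) and PSMC4 (13.4-fold; 1135 and 799.9) higher and -0.49 and -0.50 without a between-array step.

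Set against 10000 random lists of the same size and mean expression, 13 of the 39 lists with at least 5 detected members stood apart. By chance 1.95 would be expected if genes varied independently, and the percentiles describe these 2 arrays only. Those under percentile 2.5 were oxidative phosphorylation (median -3.63, percentile 0), ribosomal proteins (-3.10, 0), heat shock chaperones (-2.80, 0.32), the unfolded protein response (-2.47, 0), cell cycle (-2.32, 0.99), NRF2 genes (-2.29, 0.11), autophagy (-2.28, 0.84), housekeeping genes (-2.23, 1.32), antigen presentation (-2.15, 0.37) and hypoxia and glycolysis (-1.93, 0.77). Above stood blood and microglia markers (2.16, 99.9), HOX genes (1.24, 99.95) and TGF-beta signaling (-0.62, 98.2). The mean expression used for matching was taken over both arrays and so includes the resistant level that is compared. Genes bright on the parental array only are thereby set against genes with other patterns. The matched random medians were 1.31 for ribosomal proteins and 0.18 for oxidative phosphorylation. Low percentiles of lists bright on the parental array can follow from this matching. The HOX and blood medians turned negative without a between-array step (-1.77 and -0.58). Under cyclic loess the medians of ribosomal proteins, cell cycle, hypoxia, housekeeping and TGF-beta genes turned positive.

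Undetected values enter those medians. With genes detected on 1 array set to their bound, 35 of the 39 medians were 0, and only oxidative phosphorylation (-1.60), ribosomal proteins (-1.86), heat shock chaperones (-0.20) and housekeeping genes (-0.05) differed from it. A measure added after the data were seen, the share of a list's parental-detected probes that were also detected on the resistant array, put 0 of 38 lists under percentile 2.5 of sets matched on parental signal. It put 3 at the upper end, outside the range fixed for lists. Ribosomal protein probes were detected there more often (27 of 73, 37.0%) than matched probes (20.5%), against the sign of their median. The matching used 10 bins of parental signal. Over all probes, detection rose from 19.6% at parental signals of 2000 to 4000 to 61.0% above 16000. Very bright ribosomal probes can therefore be set against dimmer ones, and their higher share can follow from brightness. HOX (5 of 13) and WNT probes (6 of 21) were the others. Over all named probes detected on the parental array, 1566 of 12914 (12.1%) were also detected on the resistant array.

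**Figure D3:**
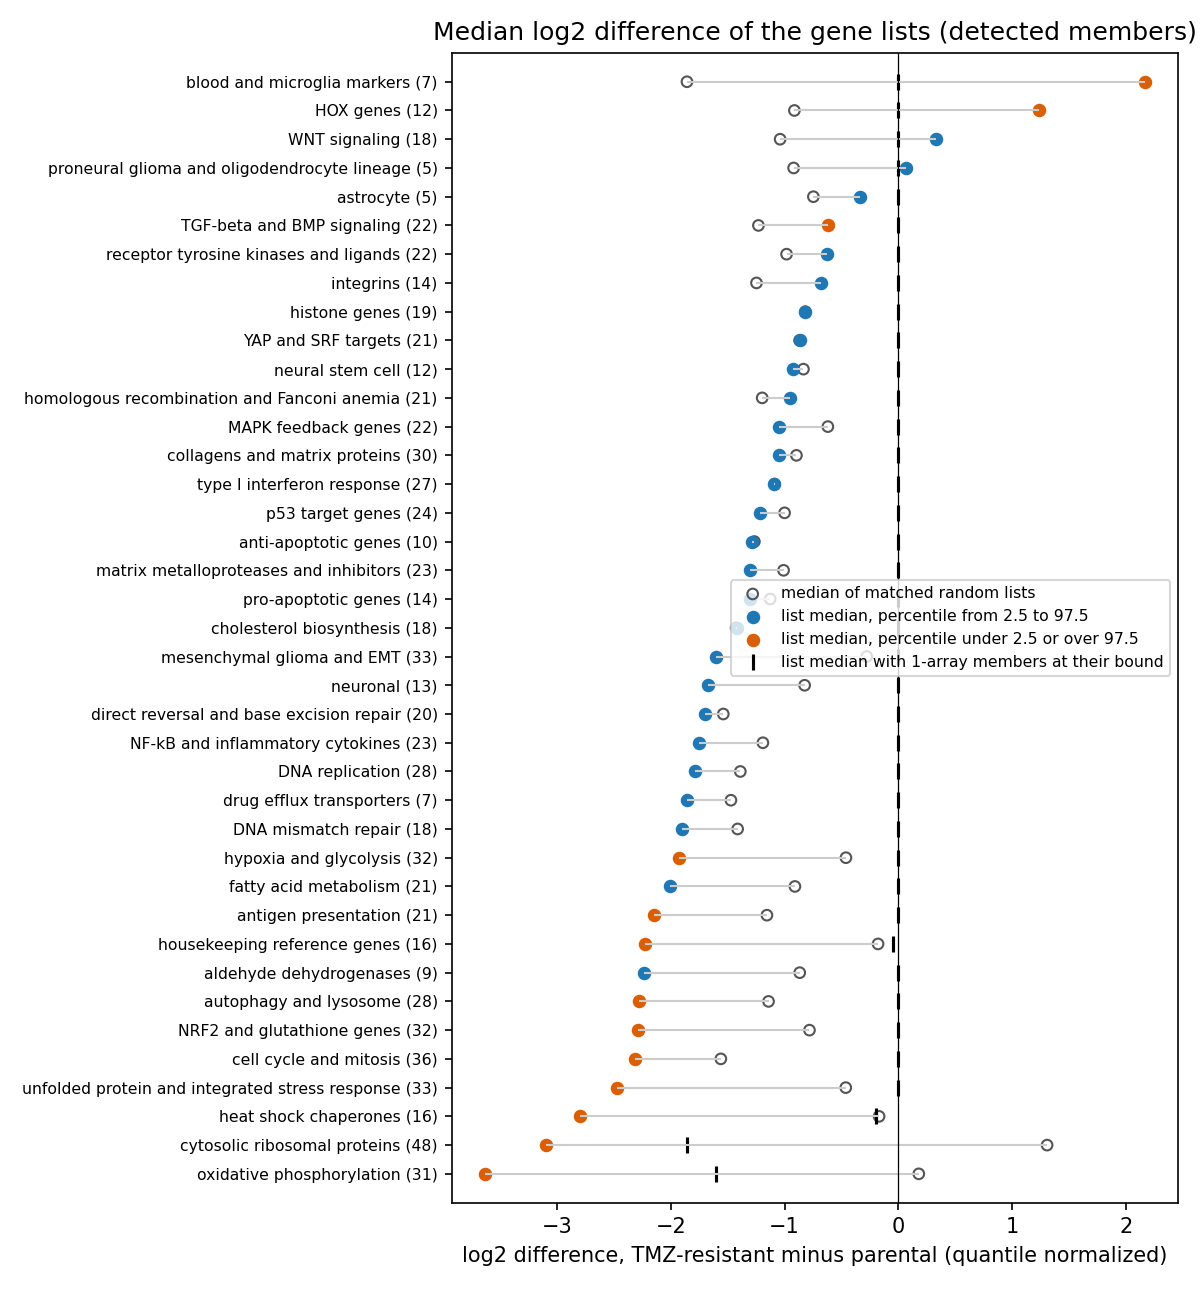
Median log2 difference (horizontal, resistant minus parental, quantile normalized) of the 39 gene lists with at least 5 detected members (vertical, number of members in parentheses). Filled points are list medians, orange where the list stood apart by its percentile, open circles are the medians of matched random lists, and black ticks are medians with genes detected on 1 array at their bound; 35 ticks lie at 0, and under other scalings list medians turn sign, such as that of HOX genes (-1.77 without a between-array step).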

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

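Probes without a gene name took no part in the comparisons, and some of them were bright on the resistant array alone. In all, 336 unnamed probes were detected on the resistant array and not on the parental one, where a detection p under 0.01 gives 140 by chance. The probe ILMN_1770854 had a signal of 5568.7 on the resistant array and 104.8 on the parental array. The probe ILMN_1742833 had 4828.5 on the resistant and 129.8 on the parental array.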

How the results depend on the processing

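The leaving out of the between-array step was chosen after seeing the data; the other settings were fixed before. Signal over background limits what the resistant array shows, since its upper quartile of signals, 90.3, lies below its lowest detected signal of 104. With the authors' table, an offset of 50, no background correction and the mean over probes, every count of higher and lower genes stayed within 1.5 times the main one. No paired analysis was possible because each group has 1 array. The causes of the shifts below were not tested unless named.

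Median centring gave 957 higher and 4364 lower genes and 1 list standing apart below, in place of 10. It turned these log2 differences negative: ALKBH2 (-0.20), IFITM2 (-1.92), MET (-0.91), MYC (-0.98), RFC4 (-0.39) and XRCC2 (-1.53), and RAD51C (-1.82) and ALDOC (-1.91), which were under 2-fold in the main setting. HOXC6 (-2.16), IFI6 (-2.76) and MSMO1 (-3.14) were also negative, but on another probe, which is the brightest under this scaling; the probes of the main setting had 2.02, 0.28 and 1.79. Of the 1548 genes higher under the main setting, 942 were also higher and 165 were lower. A detection p under 0.05 gave 2561 higher and 1249 lower genes, as more genes enter. No filter gave 4388 higher and 5278 lower genes, 6 lists standing apart above and 16 below (3 and 10 under the main setting), since undetected probes count there with their own values.

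No between-array step gave 125 higher and 8056 lower genes and 1 list standing apart below, since the lower signals of the resistant array are then not rescaled. The medians of HOX genes (-1.77) and of blood and microglia markers (-0.58) turned negative. So did the log2 differences of ALDH7A1 (-1.01), ALKBH2 (-2.30), BARD1 (-1.40), BAX (-0.19), BCL2L1 (-0.56), COL12A1 (-0.55), COL6A2 (-1.19), CPT1A (-0.40), CTNNB1 (-0.63), DDR1 (-1.09), EGR1 (-1.72), FZD7 (-0.037), H2AC25 (-0.37), HOXD3 (-0.14), ID2 (-1.55), IFITM2 (-4.02), ITGA7 (-0.26), ITGA9 (-0.60), KLF4 (-0.89), LIG3 (-0.89), MET (-3.01), MYC (-3.08), PRIM1 (-0.45), PSMB10 (-1.57), PSMC4 (-0.50), RFC4 (-2.49), SOD2 (-1.31), SREBF2 (-0.28), TUBB (-0.49) and XRCC2 (-3.63). HOXC6 (-4.27), IFI6 (-4.86) and MSMO1 (-5.24) were negative on the other probe; the probes of the main setting had no fold, -1.82 and -0.32.

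Cyclic loess gave 0 lower genes, a spread between probes of 1.62 in place of 1.004, and 0 lists standing apart above and 1 below. It turned the medians of cell cycle (0.018), hypoxia and glycolysis (0.15), TGF-beta signaling (0.014), ribosomal proteins (0.60) and housekeeping genes (0.11) positive. It also turned ANXA2P2 (0.90), ATP5F1B (1.92), CLUAP1 (1.25), FAU (1.21), LAIR1 (2.17), MSH3 (2.88), RPL35A (1.26), RPL37A (1.84), RPL38 (1.04), RPL9 (2.94), RPS6 (1.36) and TMSB4X (1.32) positive. MSMO1 was negative (-0.15) on its other probe, while the probe of the main setting had 4.66.

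Genes detected on both arrays alone gave 64 lower genes, 0 lists standing apart above and 2 below, since genes detected on 1 array leave. The medians of cell cycle (1.57), NRF2 (1.26), unfolded protein response (1.96), heat shock (1.86), hypoxia and glycolysis (1.75) and housekeeping genes (0.84) turned positive, as did ERAP2 (0.75). The probe with the smallest difference turned ERAP2 (0.75), PKM (-0.46) and TUBB (-1.77).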

Other observations

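Of the tests below, that of slowly evolving genes was laid out before its result was seen, though after the pattern that prompted it; the others, and its repeat at a signal above 200, were chosen after their results were seen. The genes named in the next paragraph were also chosen after their values were seen.

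Several of the most abundant transcripts had nearly the same signal on both arrays before any normalization. LGALS1, the galactose-binding galectin-1, had 19534 on the parental and 20611 on the resistant array, and the calcium-binding S100A6 had 13357 and 13374. Among ribosomal protein genes RPS12 had 19159 and 19701 and RPL11 had 16690.0 and 17931, while RPL8 had 17281 and 78.0. The histone variant gene H2AZ1 had 13023 and 12843, and the ferritin light chain FTL had 20787 and 15885. VIM, the intermediate filament protein vimentin, lay between, at 17596 and 527.

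Abundant parental transcripts were at background on the resistant array. Uniformly weaker labelling or hybridization would leave the brightest probes detected, yet 56.9% of the parental probes above 8000 were undetected, against 0 of them in a simulated dimmed array with as many detected probes. Changed expression in the resistant clone, as the whole cause, would keep the probes of a gene together. Beside a probe above 1000, 60.4% of the gene's other probes (110 of 182, 53.2 to 67.3%) were undetected on the resistant array, against 24.6% (513 of 2087, 22.8 to 26.5%) on the parental array. Where both probes were above 1000 on the parental array the share was 38.75% (31 of 80, 28.8 to 49.7%). It has no parental counterpart, since such probes are all detected there. Fewer probes were detected on the resistant array (6.12% against 34.0%), so more undetected partners can arise there whatever the cause. The intervals also treat the probes of a gene as independent. The comparison by itself does not decide whether changed expression was the whole cause, and changed expression of part of the genes stays open.

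A hypothesis is that the hybridised material may differ in sequence from the human probes, as RNA of another species would, so that probes of conserved sequence keep their signal. Of 210 parental-detected probes of genes known as slowly evolving, 31.9% (67) were detected on the resistant array, against 15.2% in sets matched on parental signal (percentile 100). Of 174 probes of fast-evolving genes (zinc-finger genes of chromosome 19, antigen presentation, interferon and cytokine genes) 9.77% were detected, against 12.1% (percentile 19.005), so the test as laid out did not decide; the zinc-finger probes alone were detected as often as matched ones (11.5% and 11.5%, percentile 56.5), and the others at 8.05%, against 12.6% (percentile 8.73), inside the range of matched sets too. Counting only resistant signals above 200, the percentiles were 100 for the slow and 1.79 for the pooled fast genes, but 4.62 and 9.88 for the zinc-finger and the other genes. The slow list was written from general knowledge after the brightest resistant probes had been seen, conserved genes may also differ in expression, and RNA quality and probe position were not analysed here. Matching by bins of parental signal was also coarse, since detection rose from 19.6% at signals of 2000 to 4000 to 61.0% above 16000. A list rich in very bright probes can therefore exceed its matched sets through brightness alone.

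The other pattern is that among genes detected on both arrays 1202 were called higher and 64 lower. Without the between-array step 9.39% of such calls were higher (77 higher, 743 lower). This does not decide whether the normalization made the balance, because any dimmer array gives that outcome: an unchanged simulated dimmed array gave 0 higher and 1689 lower of 1704 genes. With quantile normalization that simulated array gave 160 higher and 1 lower of 1740, against 1202 and 64 of 1437 measured. A uniformly dimmed array largely keeps the order of its probes, unlike the resistant array. The gap therefore does not show how much the normalization contributed. The normalization, a change of expression in the clone and hybridised material of differing sequence cannot be told apart here.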
